A study of Mus musculus with 6 samples.

How the data were processed

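Liver RNA of male mice was measured on a 3' expression microarray with 45101 probe sets, 1 array per mouse sample. The labels give 3 samples of the strain C57BL/KS (BKS) and 3 of the New Zealand Obese strain (NZO), all 18 weeks old and kept on chow. Per the labels' protocols, snap-frozen liver pieces were extracted with a spin-column kit and 8 ug of total RNA went into each biotin-labelled cRNA. The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, quantile-normalizes probes across arrays and summarises each probe set on the log2 scale. No versions are given in the sources used here, nor whether other arrays were normalized together with these 6. Values carry no detection call, so a low value is read only as a level near the bottom of the scale. The number of arrays limits the precision.

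Arrays were assigned to strains by their strain label. Replicate numbers 1 to 3 are names in accession order and pair nothing. The titles number the animals, but only number 1 occurs in both strains. The design text calls the animals littermates without saying which ones belong together. The labels do not say in so many words that each array is a separate animal, and if any were not, p-values would measure only the spread between these samples.

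Probe sets were named from a table of the array's platform annotation. Of the 45101 probe sets, 34945 had exactly 1 gene symbol, 932 had several and were not named, and 9211 were not listed there and stay unnamed here. The 64 control probe sets were left out of all tests. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18194 genes. Of these, 18032 matched a gene of the reference annotation GRCm38.p6, used only for names and for which genes are neighbours, and 162 kept the symbol of the array table. No genome build applies to the files, so no coordinates are given.

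The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, all 6 arrays, no covariate, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all 18194 genes, and a gene passed at an adjusted p below 0.05. Every log2 fold change is NZO minus BKS, so a positive value means higher in NZO. There were 47 gene lists, of which 11 follow the series title (peroxisomes, mitochondria and PPAR alpha targets), 9 other metabolism, 12 stress and regulation and 15 cell types. They hold 1211 entries, 1082 of them measured, and 129 not analysed here. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 47 lists. Camera compares a list with all other genes. Estimated correlations and fry's rotation test were run as alternatives. Counts of members past the test are given over all genes and adjusted over the list alone.

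Genes were named by a fixed rule. It takes the 10 highest and the 10 lowest log2 fold changes among genes past the test whose strains do not overlap and whose higher mean is at least 6, without symbols of predicted genes or clones. For each list described it takes up to 4 members past the test with the largest change or, where none passed, the 2 with the smallest p. It adds 19 genes of lipid and glucose metabolism whatever their result, of which 2 are not analysed here, and all members past the test where a count is 5 or fewer. Lists, rule, tests and most alternatives were fixed before the data were examined.

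The control probe sets then showed that the array titled number 1 in each strain (BKS replicate 1 and NZO replicate 1) stood apart from the other 4. A fit with this array batch as a block, and a comparison of 2 against 2 arrays without the number 1 arrays, were therefore added after seeing the data. The batch of number 1 arrays holds 1 array per strain, so it gives a difference and no test.

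The tests were checked on simulated data with the same 18194 genes, 3 against 3 arrays, and 100 genes changed by each of 2 sizes. Without a batch, 6% of changes of 1 on the log2 scale and 56% of changes of 2 were recovered, with 3 false calls among 65. With a simulated batch of 1 array per strain, the fit without a block recovered 2% and 57%, and the fit with the block 49% and 85%. The simulated batch shifted each gene alike in both strains, as the block assumes. In the data, the deviations of the number 1 arrays from their strain means correlated at 0.42. The gain from the block in the simulation therefore need not hold for the data. Alternatives changed the normalization, the filter on dim genes, the choice of probe set, the variance model, array weights and the arrays included. No 2 arrays held identical columns. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.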

Results

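Gene expression was measured in whole liver of 18-week-old male mice of 2 inbred strains. NZO mice become obese and develop diabetes and other features of the metabolic syndrome on ordinary chow, and BKS mice served as the control strain. The series title places the interest in liver peroxisomes and mitochondria. Each strain had 3 arrays. Array medians lay between 5.08 and 5.22 on the log2 scale. Correlations between arrays were 0.976 to 0.994 within a strain and 0.962 to 0.982 between strains.

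The first principal component held 56.7% of the variance over 9622 genes and set NZO replicate 1 apart. On the second, with 24.99%, NZO replicates 2 and 3 lay at -29.8 and -27.3 and the other 4 arrays, NZO replicate 1 among them, between 5.65 and 30.1. The spiked-in hybridization controls, which contain no liver RNA, averaged 9.68 in BKS replicate 1 and 8.45 in NZO replicate 1, against 10.6 to 11.8 on the other 4 arrays. These are the arrays titled number 1 in each strain. Beta-actin 3' minus 5' signal, a sign of RNA or cDNA truncation, was 1.72, 2.33 and 1.92 in BKS and 1.29, 1.34 and 1.39 in NZO. The 18S ribosomal RNA control reached 11.9 and 9.47 in BKS replicates 2 and 3 and at most 6.14 on the other arrays. All 3 BKS arrays thus lay above all 3 NZO arrays in the beta-actin measure. The same measure for Gapdh was 0.77, 0.98 and 0.45 in BKS and -0.04, 0.11 and 0.14 in NZO. These 2 measures of RNA quality therefore moved with strain, while the hybridization controls separated the number 1 arrays from the rest. The comparison of 2 against 2 arrays sets BKS replicates 2 and 3, with their high 18S signal, against NZO replicates 2 and 3 (6.14 and 5.38). In it, 18S signal and beta-actin truncation cannot be separated from strain.

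**Figure D1:**
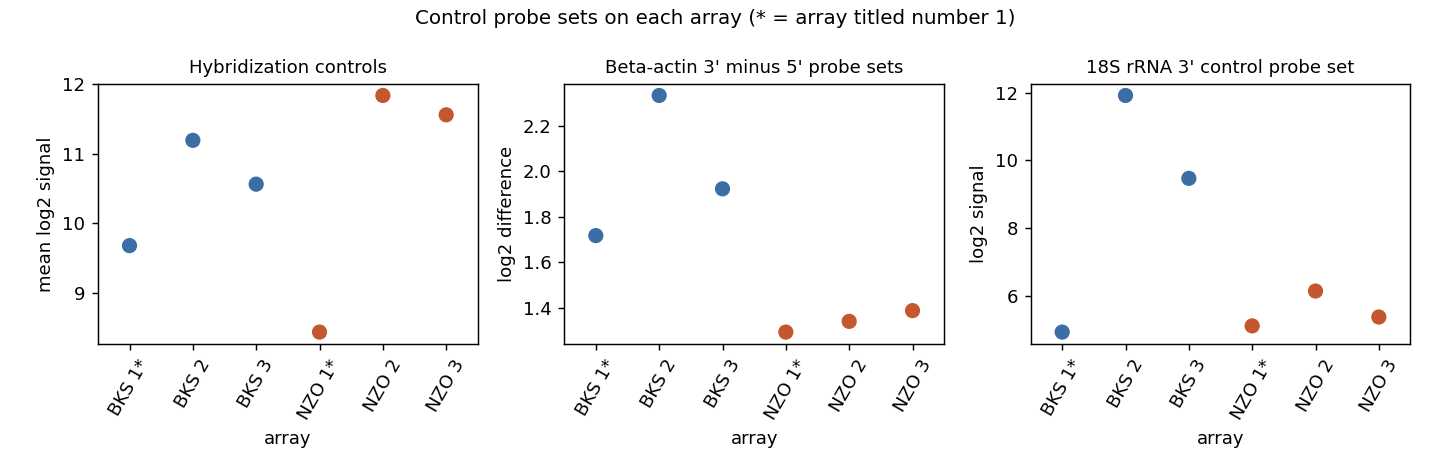
Log2 signal of control probe sets on each of the 6 arrays (blue, BKS; orange, NZO; 1 point per array; the asterisk marks the arrays titled number 1). Hybridization controls averaged 9.68 and 8.45 on the marked arrays and 10.6 or more on the others, and the beta-actin difference was 1.29 to 1.39 in NZO and 1.72 to 2.33 in BKS.

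The strains differed at 135 of 18194 genes, of which 59 were higher and 76 lower in NZO. Among the large increases were the fatty acid hydroxylase Cyp4a14 (97.4-fold), the cytochrome P450 Cyp2c39 (58.7-fold), the protease cathepsin E (Ctse, 32.0-fold), the muscle protein myomesin 2 (Myom2, 22.4-fold) and the fatty acid transporter Cd36 (19.7-fold). Among the large decreases were the cytochrome P450 Cyp2c37 (54.5-fold), Rpgrip1 (35.3-fold), Wfdc21 (23.1-fold), Nlrp12 (16.6-fold) and Xaf1 (15.7-fold). The lower strain's mean lay near the array medians for Cyp4a14 (5.38), Cyp2c39 (5.61), Rpgrip1 (5.46), Nlrp12 (5.69) and Xaf1 (5.76), and Cyp2c37 was at 4.26 in NZO replicate 1. Without detection calls, the size and order of these folds depend on such low values. In all 135 genes the 3 values of one strain lay above the 3 of the other, as they did in 16.97% of all genes, where chance gives 10%. With the array batch as a block 275 genes were higher and 917 lower, including all 135. The block is balanced between the strains, so it leaves every log2 fold change unchanged and acts only on the error estimate. Among the 2 against 2 arrays 363 were higher and 549 lower. Second probe sets of Xaf1 and Rpgrip1 gave log2 fold changes of 1.17 (adjusted p = 0.112), the opposite direction, and -0.08 (adjusted p = 0.898), against -3.97 and -5.14. That of Rpgrip1 averaged below 6, so it may be too dim to show the change. A second probe set of Ctse gave a smaller log2 fold change, 2.22 (adjusted p = 0.107) against 5.00. Myom2 lay near the bottom of the scale in BKS (3.86 ± 0.24, SD, n = 3), with 3.03 from its second probe set (adjusted p = 0.00243). Without BKS replicate 1, 2 or 3, the higher and lower counts were 34 and 62, 13 and 14, and 10 and 18, and without NZO replicate 1, 2 or 3 they were 150 and 108, 29 and 60, and 18 and 18.

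The clearest group was the PPAR alpha targets, genes that this fatty acid sensing receptor switches on. Of 26 measured members, 6 rose in NZO, none fell and 20 did not pass, or 11 and 0 adjusted over the list alone. The mean log2 fold change was 1.14 and the median 0.53, with 21 members above 0 (camera adjusted p = 8.82e-13, and adjusted p = 0.854 with an estimated correlation). Cyp4a14 went from 5.38 ± 0.83 (SD, n = 3) in BKS to 11.98 ± 0.81 in NZO, a log2 fold change of 6.61 with a standard error of 0.51 and adjusted p = 0.00305. Cd36 rose from 5.97 ± 0.85 to 10.27 ± 0.84 (log2 fold change 4.30, standard error 0.53, adjusted p = 0.0184). Acot3, a peroxisomal acyl-CoA thioesterase, rose by 2.99 (standard error 0.48, adjusted p = 0.0482), and Pdk4, which restrains pyruvate oxidation, by 2.52 (standard error 0.30, adjusted p = 0.0160). Acot3 was measured only by a shared-sequence probe set (ending in _s_at), so its signal may not come from Acot3 alone. The same limit holds where Acot3 is counted in the peroxisomal and female-biased lists. Ppara itself was at 10.60 ± 0.31 in BKS and 10.58 ± 0.77 in NZO (adjusted p = 0.989). Cyp4a14 passed with any single array left out. Cd36 did not pass without BKS replicate 1, 2 or 3 or NZO replicate 2 or 3 (adjusted p = 0.0569, 0.0900, 0.0557, 0.0566 and 0.126), and Acot3 did not without any BKS replicate or NZO replicate 2 (adjusted p = 0.0630, 0.280, 0.230 and 0.118). With 1 array left out, the log2 fold change ran from 3.86 to 4.75 for Cd36 and from 2.63 to 3.51 for Acot3. A second probe set of Cd36 gave 4.62 (adjusted p = 0.0165).

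**Figure D2:**
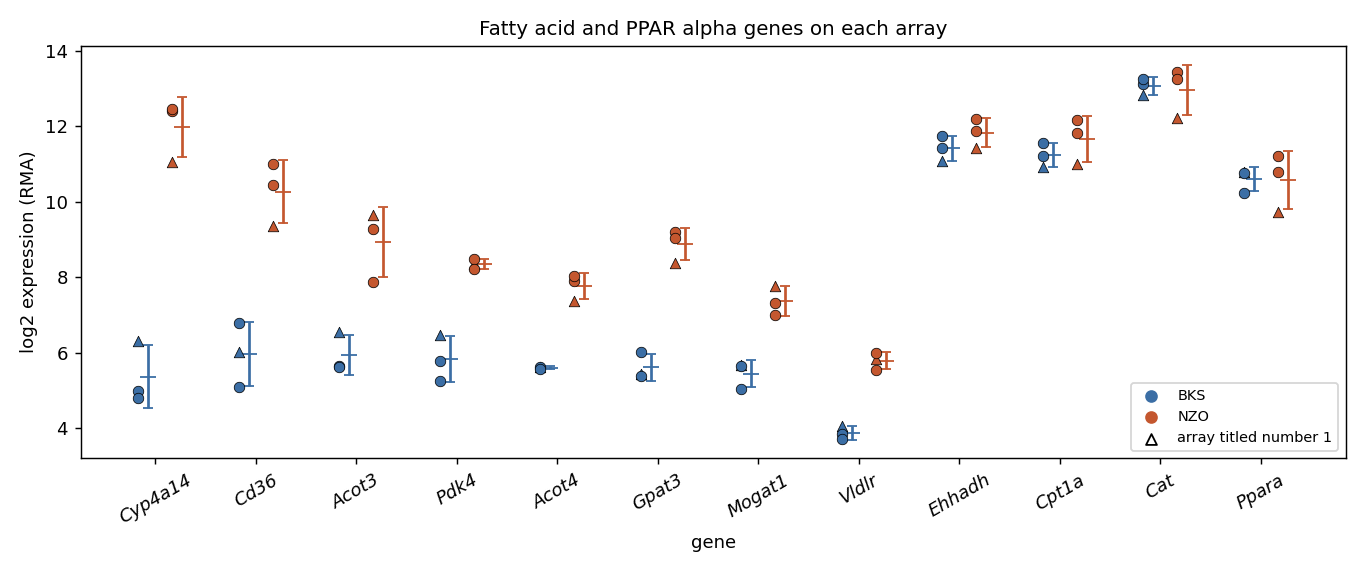
Log2 expression of 12 genes of fatty acid metabolism on each array (blue, BKS; orange, NZO; triangles, arrays titled number 1; the bar beside each group is its mean ± SD, n = 3). Cyp4a14 averaged 5.38 in BKS and 11.98 in NZO, while Ppara averaged 10.60 and 10.58.

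Among peroxisomal genes, a few single members passed. Of 27 genes of peroxisomal fatty acid oxidation, 2 rose, Acot3 and its relative Acot4 (log2 fold change 2.17, standard error 0.20, adjusted p = 0.00640, and 0.81 with adjusted p = 0.398 from its second probe set), none fell and 25 did not pass, or 6 higher and 1 lower adjusted over the list alone. Both are acyl-CoA thioesterases and do not carry out the oxidation steps. The second probe set of Acot4 averaged below 6, so it may be too dim to show the change. The list mean was 0.28 and its median 0.05 (camera adjusted p = 0.0178, and adjusted p = 0.854 with an estimated correlation). The oxidation enzyme Ehhadh (0.42, adjusted p = 0.602) and the hydrogen peroxide-degrading Cat (-0.10, adjusted p = 0.947) did not pass. Among 22 genes of peroxisome biogenesis and division none passed, or 1 lower adjusted over the list alone (mean -0.16, camera adjusted p = 0.566). That mean was -0.32 without NZO replicate 2 and 0.105 without NZO replicate 1, where the list did not pass either (adjusted p = 0.183 and 0.506). The values with the smallest p were Pex6 at -1.34 (adjusted p = 0.0775, and 0.00195 with the block) and Slc25a17 at 0.81 (adjusted p = 0.452, and 0.0392 with the block). The division factor Pex11a was at 0.17 (adjusted p = 0.882). Of 24 redox and other matrix genes, 1 fell, the coenzyme A hydrolase Nudt19 (-1.64, adjusted p = 0.0232, and -0.84 with adjusted p = 0.299 from its second probe set), also adjusted over the list alone (mean -0.21, camera adjusted p = 0.189). With the block, 5 members of the fatty acid oxidation list were higher and 1 lower. That list did not pass without BKS replicate 1 (adjusted p = 0.0695) or NZO replicate 2 (adjusted p = 0.136). It stood at 0.43 among the 2 against 2 arrays and -0.02 between the number 1 arrays. The matrix list passed without NZO replicate 2 (mean -0.40, adjusted p = 0.0362).

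Lists of mitochondrial respiratory chain genes were lower, with no single member past the test over the 6 arrays without a block. None of 33 complex I genes passed, over all genes or adjusted over the list alone. Their mean was -0.42, with 2 members above 0 (camera adjusted p = 0.000319, and adjusted p = 0.854 with an estimated correlation). With the block 3 complex I genes, 2 of complexes II to V and 4 of mitochondrial biogenesis and dynamics were lower, and among the 2 against 2 arrays 3 of biogenesis and dynamics and none of the others. Ndufs8 was at -0.78 (adjusted p = 0.220, and 0.0413 with the block) and Ndufv3 at -0.68 (adjusted p = 0.279). None of 39 genes of complexes II to V passed, over all genes or adjusted over the list alone (mean -0.29, camera adjusted p = 0.0101, and adjusted p = 0.876 with an estimated correlation). Relative to other genes, camera placed complexes II to V higher instead with repeated quantile normalization (mean -0.014, adjusted p = 0.977) and cyclic loess (mean 0.061, adjusted p = 0.247), without a call. Cox6b1 was at -0.64 (adjusted p = 0.258, and 0.0359 with the block) and Atp5d at -0.52 (adjusted p = 0.326). Nor did any of 26 genes of mitochondrial biogenesis and dynamics pass over all genes or adjusted over the list alone (mean -0.37, camera adjusted p = 0.00859, and adjusted p = 0.854 with an estimated correlation). Polrmt was at -0.80 (adjusted p = 0.200, and 0.0356 with the block) and Ppargc1b at -0.80 (adjusted p = 0.195, and 0.0321 with the block). Ppargc1a was at -0.06 (adjusted p = 0.916) and Nnt at 0.06 (adjusted p = 0.963). Without NZO replicate 1 the 3 means were -0.10, 0.02 and -0.17 and none passed (adjusted p = 0.0649, 0.988 and 0.110). Among the 2 against 2 arrays they were -0.20, -0.07 and -0.29, where complex I (adjusted p = 0.0108) and biogenesis (adjusted p = 0.0133) passed and complexes II to V did not (adjusted p = 0.351). The number 1 arrays alone differed by -0.85, -0.72 and -0.54.

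Other mitochondrial lists did not pass. The 31 genes of mitochondrial fatty acid oxidation had a mean of 0.02 and a median of -0.02 (camera adjusted p = 0.396) and no member past the test, over all genes or adjusted over the list alone. Acot2 was at 1.08 (adjusted p = 0.146, and 0.0335 with the block), Acad9 at 0.64 (adjusted p = 0.539) and Cpt1a at 0.43 (adjusted p = 0.683). Without NZO replicate 1 that mean was 0.33 and the list passed (adjusted p = 0.000227), as it did with repeated quantile normalization (0.27), with cyclic loess (0.32) and among the 2 against 2 arrays (0.20, adjusted p = 0.0133). The 7 ketone body genes averaged 0.27 (camera adjusted p = 0.0734), with none past the test over all genes and 2 higher adjusted over the list alone. Slc16a6 was at 1.18 (adjusted p = 0.0952, and 0.0145 with the block) and the hormone Fgf21 at 0.59 (adjusted p = 0.192). The list passed without BKS replicate 2 (0.36, adjusted p = 0.0262), BKS replicate 3 (0.34, adjusted p = 0.0309) or NZO replicate 1 (0.44, adjusted p = 0.0166), and in a rotation test (fry) with the block (adjusted p = 0.0291). It did not pass in fry without the block (adjusted p = 0.749) or in camera with an estimated correlation, without or with the block (adjusted p = 0.854 and 0.891). Among 24 citric acid cycle genes Pdk4 rose, with 1 higher and 1 lower adjusted over the list alone (list mean -0.09, camera adjusted p = 0.611). The list mean was 0.23 without NZO replicate 1 and -0.295 without NZO replicate 2, and neither passed (adjusted p = 0.11 and 0.115). The 15 mitochondrial redox and uncoupling genes averaged -0.13 (camera adjusted p = 0.611), with none past the test, over all genes or adjusted over the list alone. Their mean was 0.13 without NZO replicate 1 and -0.27 without NZO replicate 2 or 3, and the list did not pass there. Sod2 was at -0.72 (adjusted p = 0.395, and 0.0402 with the block) and Txnrd2 at -0.42 (adjusted p = 0.566).

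**Figure D3:**
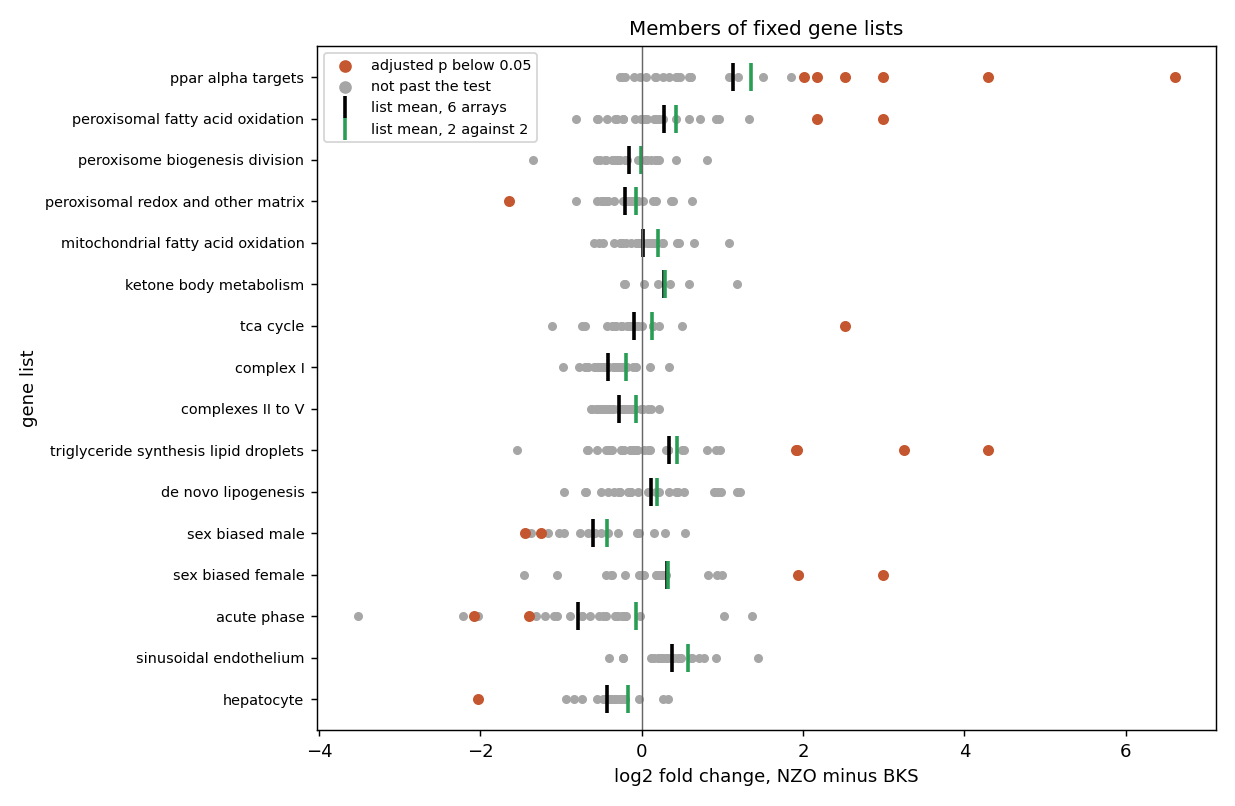
Log2 fold change (NZO minus BKS) of each member of 16 fixed gene lists (orange, adjusted p below 0.05; grey, not past the test), with the list mean over 6 arrays (black) and over the 2 against 2 arrays (green). The PPAR alpha target mean is 1.14, the complex I mean -0.42 over 6 arrays and -0.20 among the 2 against 2 arrays.

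A few genes of fatty acid uptake and triglyceride synthesis rose. Of 35 genes of triglyceride synthesis and lipid droplets, 4 rose, none fell and 31 did not pass, or 6 higher and 2 lower adjusted over the list alone. They were Cd36, the acyltransferases Gpat3 (log2 fold change 3.25, standard error 0.27, adjusted p = 0.00353) and Mogat1 (1.92, standard error 0.26, adjusted p = 0.0286), and the lipoprotein receptor Vldlr (1.91, standard error 0.18, adjusted p = 0.00648), whose second probe set gave 0.39. Vldlr lay near the bottom of the scale in BKS (3.88, against 5.8 in NZO). Its second probe set averaged below 6, so the size of its change is uncertain. The list mean was 0.34 and its median -0.06 (camera adjusted p = 0.0402, and adjusted p = 0.854 with an estimated correlation). It did not pass with the array batch as a block (adjusted p = 0.0722), where 6 members were higher and 1 lower, with array weights (adjusted p = 0.0874), without BKS replicate 1 (adjusted p = 0.108) or without NZO replicate 2 (adjusted p = 0.163). The droplet proteins Plin2 (-0.10, adjusted p = 0.918) and Cidec (-0.15, adjusted p = 0.809) did not pass, nor did Pparg (-0.22, adjusted p = 0.861). Cidec lay below the array medians in both strains (4.57 in BKS and 4.42 in NZO), which leaves little signal to compare.

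None of 28 genes of fatty acid synthesis passed, or 1 lower adjusted over the list alone (mean 0.12, camera adjusted p = 0.216). The list passed as higher with repeated quantile normalization (0.38, adjusted p = 0.00204), with cyclic loess (0.41, adjusted p = 0.00139) and without BKS replicate 3 (0.26, adjusted p = 0.0293). Elovl3 was at -0.97 (adjusted p = 0.0945, and 0.0217 with the block), Me1 at 0.89 (adjusted p = 0.159, and 0.0317 with the block), Fasn at 0.22 (adjusted p = 0.781), Scd1 at -0.14 (adjusted p = 0.863) and the regulator Srebf1 at -0.28 (adjusted p = 0.808). In glucose output, with 23 genes and a mean of 0.06 (camera adjusted p = 0.396), Ppp1r3c was at 1.89 (adjusted p = 0.0940, and 0.0170 with the block), Foxo1 at -1.37 (adjusted p = 0.0775, and 0.0133 with the block) and Pck1 at -0.56 (adjusted p = 0.787). In that list 2 genes were higher and 1 lower adjusted over the list alone. The glucose-6-phosphatase gene G6pc was at 1.11 (adjusted p = 0.151) and passed with the block (adjusted p = 0.0356). The glucose output list passed with repeated quantile normalization (0.29, adjusted p = 0.00339) and cyclic loess (0.33, adjusted p = 0.00143), and so did the lipoprotein list (0.29, adjusted p = 0.0232, and 0.36, adjusted p = 0.00143). The glucose output list also passed without NZO replicate 1 (0.30, adjusted p = 0.0132) and among the 2 against 2 arrays (0.27, adjusted p = 0.0469), and so did the lipoprotein list (0.39, adjusted p = 0.00144, and 0.32, adjusted p = 0.0206). Without NZO replicate 2 or 3 both means were negative and did not pass (glucose output -0.075 and -0.053, lipoproteins -0.17 and -0.13). Among lipoprotein genes Apoa4 rose (2.22, standard error 0.33, adjusted p = 0.0391, and 2.93 with adjusted p = 0.133 from its second probe set), with 2 of 21 higher adjusted over the list alone (list mean 0.03, camera adjusted p = 0.593). Among bile acid and sterol transport genes the transporter Abcc4 rose (2.82-fold, adjusted p = 0.0446), with 2 of 28 higher and 1 lower adjusted over the list alone (mean -0.13, camera adjusted p = 0.332). Abcc4 averaged 4.45 in BKS, below the array medians, and 5.95 in NZO, so the size of its fold depends on a low value.

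Further genes among the 10 highest were Mrap2 (log2 fold change 3.16), the steroid dehydrogenase Akr1c18 (3.16) and Hddc3 (2.96). Those among the 10 lowest were the peptidase Mme (-3.77), Cap1 (-3.41), Serpina4-ps1 (-3.31), the immediate early transcription factor Egr1 (-3.30) and Zfp874a (-3.13). Among 22 drug-metabolizing genes, Cyp2c39 rose and Cyp2c37 and Cyp2c55 (-1.61) fell, or 2 higher and 4 lower adjusted over the list alone (list mean -0.25, camera adjusted p = 0.409). Second probe sets of Hddc3 (0.27) and Mme (-0.68) showed little of the change, and those of Cap1 (-2.59, adjusted p = 0.0593) and Serpina4-ps1 (-2.85, adjusted p = 0.0866) did not pass. Those of Hddc3, Mme and Cap1 averaged below 6, so they may be too dim to show the full change. Of the 40 named genes past the test, 17, 28 and 27 no longer passed without BKS replicate 1, 2 or 3, and 18 and 23 without NZO replicate 2 or 3, while all 40 passed without NZO replicate 1 and with the block. Another 29 named genes did not pass over the 6 arrays but did with the block.

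The list of liver genes that are normally higher in males was shifted downward in NZO. Of 20 measured, 2 fell, the steroid dehydrogenase Hsd3b5 (-1.44, adjusted p = 0.0424) and Cyp2d9 (-1.25, adjusted p = 0.0413), none rose and 18 did not pass, or 6 lower adjusted over the list alone (mean -0.61, camera adjusted p = 7.74e-05, and adjusted p = 0.854 with an estimated correlation). Of 23 female-biased genes, 2 rose, the hepcidin gene Hamp2 (1.94, adjusted p = 0.00346) and Acot3, or 3 higher and 1 lower adjusted over the list alone (mean 0.31, camera adjusted p = 0.0179, and adjusted p = 0.854 with an estimated correlation). A second probe set of Hamp2 gave 0.05, but it averaged below 6 and may be too dim to show the change. The female-biased list did not pass without NZO replicate 1 (adjusted p = 0.0570), with cyclic loess (adjusted p = 0.0630), with array weights (adjusted p = 0.0874) or without shared-sequence probe sets (0.11, adjusted p = 0.229). With the block 7 male-biased genes were lower. The male-biased mean was -0.98 between the number 1 arrays and -0.43 among the 2 against 2. It was -0.34 without NZO replicate 1, -0.34 with repeated quantile normalization and -0.28 with cyclic loess, and passed each time.

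The list of acute phase genes, which the liver makes in inflammation, was shifted downward over the 6 arrays but not among the 2 against 2. Of 28 measured, 2 fell, the receptor Il1r1 (-2.08, but 0.21 with adjusted p = 0.677 from its second probe set) and the serum amyloid gene Saa3 (-1.40, adjusted p = 0.0113), or 5 adjusted over the list alone (mean -0.79, camera adjusted p = 6.63e-06, and adjusted p = 0.854 with an estimated correlation). That second probe set of Il1r1 averaged below 6, so its opposite sign may rest on little signal. With the block 6 members of the list were lower. The list averaged 12.27, 11.54 and 11.18 in BKS and 10.03, 11.55 and 11.04 in NZO. The number 1 arrays differed by -2.24, while the mean was -0.07 among the 2 against 2 arrays and did not pass (adjusted p = 0.222). Without BKS replicate 1 alone it was -0.49 (adjusted p = 0.00510) and without NZO replicate 1 alone -0.37 (adjusted p = 0.00144), and both passed. Of 26 genes of the unfolded protein and integrated stress responses none passed, or 1 lower adjusted over the list alone (mean -0.39, camera adjusted p = 0.0402, and adjusted p = 0.876 with an estimated correlation). Chac1 was at -1.59 (adjusted p = 0.0912, and 0.0142 with the block) and Creld2 at -1.59 (adjusted p = 0.377, and 0.0172 with the block). With the block 5 members were lower. That list did not pass under repeated quantile normalization (-0.20, adjusted p = 0.131), cyclic loess (-0.15, adjusted p = 0.188) or 6 other settings, without BKS replicate 2 or 3 or NZO replicate 1 (adjusted p = 0.0765, 0.0837 and 0.655) or among the 2 against 2 arrays (-0.23, adjusted p = 0.134). None of 33 proliferation genes passed, over all genes or adjusted over the list alone (mean 0.26, camera adjusted p = 0.000319, and adjusted p = 0.854 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle, was at 1.94 (adjusted p = 0.150, and 0.0258 with the block) and Mcm7 at -0.81 (adjusted p = 0.168, and 0.0218 with the block). Only 7 of the 33 had a mean of at least 6, and the list mean was 0.00 between the number 1 arrays, 0.39 among the 2 against 2 and 0.17 without NZO replicate 2.

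Marker lists of 2 other cell types, sinusoidal endothelium and skeletal muscle, were shifted upward and that of hepatocytes downward. None of 22 sinusoidal endothelium markers passed over all genes, and 4 were higher adjusted over the list alone. Their mean was 0.38, with 19 members above 0 (camera adjusted p = 1.29e-05, and adjusted p = 0.854 with an estimated correlation). Ehd3 was at 1.44 (adjusted p = 0.0775, and 0.00441 with the block) and Pecam1 at 0.71 (adjusted p = 0.132, and 0.0297 with the block). Pecam1 averaged below the array medians in both strains (4.33 in BKS and 5.04 in NZO). The endothelial mean was -0.02 between the number 1 arrays, 0.57 among the 2 against 2 and 0.21 without NZO replicate 2. Among 21 hepatocyte markers the transcription factor Foxa1 fell (-2.03, adjusted p = 0.0206), or 2 adjusted over the list alone (mean -0.44, camera adjusted p = 0.00507, and adjusted p = 0.854 with an estimated correlation). The hepatocyte list did not pass with repeated quantile normalization (-0.19, adjusted p = 0.216), cyclic loess (-0.10, adjusted p = 0.958), array weights (-0.23, adjusted p = 0.119), the second probe set (-0.11), without NZO replicate 1 (-0.14, adjusted p = 0.258) or among the 2 against 2 arrays (-0.17, adjusted p = 0.360). The number 1 arrays differed by -0.98. Among 20 skeletal muscle markers nebulin (Neb) rose (1.54, adjusted p = 0.0141), also adjusted over the list alone (mean 0.17, camera adjusted p = 0.0178, and adjusted p = 0.854 with an estimated correlation). The muscle list did not pass with repeated quantile normalization (adjusted p = 0.131), cyclic loess (adjusted p = 0.181), without NZO replicate 1 (adjusted p = 0.0771) or among the 2 against 2 arrays (adjusted p = 0.0596). Only 4 of its 20 members had a mean of at least 6.

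No Kupffer cell marker passed, over all genes or adjusted over the list alone (19 markers, mean 0.20, camera adjusted p = 0.0570), with Folr2 at 0.43 (adjusted p = 0.348) and Hmox1 at 0.83 (adjusted p = 0.354). Among the 2 against 2 arrays the list mean was 0.58 and passed (adjusted p = 2.83e-06), as it did without BKS replicate 1 (0.36, adjusted p = 0.00142), NZO replicate 1 (0.42, adjusted p = 0.00157) or NZO replicate 3 (0.18, adjusted p = 0.0327). It also passed with repeated quantile normalization (0.27, adjusted p = 0.0176), median centring (0.14, adjusted p = 0.0329), cyclic loess (0.32, adjusted p = 0.0131), the dim filter (0.21, adjusted p = 0.0267), the mean of probe sets (0.22, adjusted p = 0.0391) and array weights (0.38, adjusted p = 0.00655). It did not pass without BKS replicate 2 (0.15, adjusted p = 0.173), BKS replicate 3 (0.097, adjusted p = 0.345) or NZO replicate 2 (-0.003, adjusted p = 0.521), or with an estimated correlation (adjusted p = 0.876). The number 1 arrays differed by -0.56. None of 32 stellate cell and fibroblast markers passed, over all genes or adjusted over the list alone (mean 0.03, camera adjusted p = 0.189), with Col3a1 at -1.17 (adjusted p = 0.240) and Col4a2 at -0.94 (adjusted p = 0.274, and 0.0217 with the block). That list passed with array weights (0.21, adjusted p = 0.0268), without BKS replicate 1 (0.20, adjusted p = 0.00131) and among the 2 against 2 arrays (0.32, adjusted p = 0.000134), where the number 1 arrays differed by -0.55.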

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

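Of 10092 probe sets without a single gene name, which enter no gene-level comparison, 11 were higher and 9 lower in NZO than in BKS by the same limma test (adjusted p below 0.05). They were picked out because they carry a strain difference in data outside the gene-level comparison. The highest log2 fold change among them was 4.465, from 7.99 in BKS to 12.46 in NZO (adjusted p = 0.012), a level at which the signal stands well above the bottom of the scale in both strains. No explanation for these probe sets was tested.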

How the results depend on the processing

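The block, alone or with another set test, and the 2 against 2 comparison were chosen after seeing the data. No paired analysis was possible because the titles share only the number 1 between the strains. Against 59 genes higher and 76 lower, repeated quantile normalization gave 192 and 235, cyclic loess 208 and 221, an intensity trend with robust eBayes 121 and 160, array weights 398 and 898, the array batch as a block 275 and 917, the 2 against 2 arrays 363 and 549, and the second brightest probe set (9009 genes) 17 and 24. Leaving out 1 array gave 10 to 150 higher (lowest without BKS replicate 3, highest without NZO replicate 1) and 14 to 108 lower (without BKS replicate 2 and without NZO replicate 1). Median centring, the dim-gene filter, the mean of a gene's probe sets, leaving out shared-sequence probe sets, testing every probe set and a minimum log2 fold change of 1 stayed within 1.5 times. The share of higher calls was 43.7% in the main comparison, 48.5% with cyclic loess and 38.4% with median centring, but 23.1% with the block, 30.7% with array weights, 32.6% without NZO replicate 2 and 58.1% without NZO replicate 1. The second probe set of Il1r1 gave 0.21 and that of Xaf1 1.17, the opposite sign to the brighter one. The second-probe fit covers fewer genes, and for the other moves the cause was not tested. Of the 40 named genes past the test, all 40 kept direction and call with quantile normalization, the dim filter, array weights, the block and 2 against 2, and 39 did with cyclic loess, 38 with the intensity trend, 35 with the mean of probe sets and 34 with median centring, with no reversal among these. The block, the dim filter and the intensity trend leave each gene's log2 fold change unchanged, so no reversal was possible under them. Of the 17 with a second probe set, 2 kept the call, 13 lost it and 2 reversed, and of the 34 measured without shared-sequence probe sets 29 kept the call and 5 lost it. Of these 17 second probe sets, only those of Nudt19, Apoa4, Cd36, Ctse, Gbp7, Serpina4-ps1 and Xaf1 averaged at least 6, and among them only Cd36 kept its call. The rest may be too dim to keep a call. Among all called genes with a second probe set of mean at least 6, its sign was the same in 19 of 21 lower and 8 of 8 higher ones. Of the 68 named genes not past the test, 30 passed with array weights, 29 with the block, 23 in 2 against 2, 12 with cyclic loess, 11 with quantile normalization, 9 with the intensity trend, 3 with the dim filter, 1 with the mean of probe sets and 2 of 39 with the second probe set.

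Of the lists, 14 passed, 7 higher and 7 lower. This split was 14 and 3 with quantile normalization, 14 and 2 with cyclic loess, 9 and 4 with array weights, 12 and 2 without NZO replicate 1, 6 and 13 without NZO replicate 2, 6 and 7 with the block and 16 and 3 in 2 against 2. The total was 9 without probe sets ending in _x_at, _s_at or _a_at, 5 with the second probe set, 0 with an estimated correlation, with the block and an estimated correlation, and with fry, and 1 with the block and fry, the ketone body list (0.27, adjusted p = 0.0291). Under these last 4 the calls ended for all 14, among them PPAR alpha targets (1.14, adjusted p = 0.854, 0.891, 0.214 and 0.285), peroxisomal fatty acid oxidation (0.28), complex I (-0.42), complexes II to V (-0.29) and mitochondrial biogenesis (-0.37). Camera with an estimated correlation allows for genes of a list moving together, while fry also asks another question, whether a list moves at all rather than against other genes, so the 2 are not compared here. PPAR alpha targets and male-biased genes passed under every setting run with camera at its preset correlation. The complex I mean was -0.087 with cyclic loess and -0.29 without shared-sequence probe sets, and neither passed. Complexes II to V lay higher relative to other genes with quantile normalization (-0.014, still a negative mean) and cyclic loess (0.061), and did not pass there or with the dim filter (-0.29), without shared-sequence probe sets (0.007), with the second probe set (-0.12), the intensity trend (-0.29), array weights (-0.11) or 2 against 2 (-0.07). Mitochondrial biogenesis did not pass with quantile normalization (-0.21), cyclic loess (-0.18) or the second probe set (-0.093), nor did peroxisomal fatty acid oxidation with the second probe set (0.036). Mitochondrial fatty acid oxidation passed as higher with quantile normalization (0.27), cyclic loess (0.32) and 2 against 2 (0.20), and ketone body genes with quantile normalization (0.41) and cyclic loess (0.43). With 1 array left out, the means ran from 0.16 (without NZO replicate 2) to 0.48 (without NZO replicate 1) for peroxisomal fatty acid oxidation, -0.40 to 0.096 for the peroxisomal matrix list, -0.16 to 0.33 for mitochondrial fatty acid oxidation, 0.12 (without BKS replicate 1) to 0.44 for ketone body genes, -0.58 to -0.099 for complex I, -0.44 to 0.019 for complexes II to V and -0.52 to -0.17 for mitochondrial biogenesis. Apart from the ketone body list, each lowest value came without NZO replicate 2, and each highest one came without NZO replicate 1. Among the other lists, the integrated stress call ended with median centring (adjusted p = 0.0845), the dim filter (0.0734), the mean of probe sets (0.0939), without shared-sequence probe sets (0.0550), with the second probe set (0.815) and with array weights (0.0874), the skeletal muscle call without shared-sequence probe sets (0.0550) and with the second probe set (0.663), and those of acute phase (0.289), proliferation (0.220) and endothelium (0.0629) with the second probe set. For these list calls, other than under an estimated correlation, the cause was not tested. Signal over background limits the dim genes: 18 of the genes called higher had a BKS mean below 5 and 12 of those called lower an NZO mean below 5, near the bottom of the scale.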

Other observations

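The tests of the array batch, RNA degradation, cell composition, the mitochondrial and PPAR alpha lists against brightness, and the neighbours called with the block were chosen after the results were seen. In part, acute phase genes were highest in BKS replicate 1. The iron-binding protein gene Lcn2 was at 11.51 there and at 7.45 and 6.73 in the other BKS arrays, with a mean of 5.05 ± 0.21 (SD, n = 3) in NZO. Its log2 fold change of -3.52 did not pass over 6 arrays (adjusted p = 0.279) but did with the block (adjusted p = 0.0220) and, at -2.16, among the 2 against 2 arrays (adjusted p = 0.00409), so the difference was not confined to that array. Saa1 was at 14.14, 12.11 and 12.04 in BKS and at 8.87, 13.06 and 10.27 in NZO. Cish, a feedback inhibitor of cytokine and growth hormone signalling, was lower in NZO (log2 fold change -2.46, standard error 0.39, adjusted p = 0.0444), and its relatives Socs2 (-2.26, adjusted p = 0.260) and Socs3 (-2.21, adjusted p = 0.151) did not pass, though Socs3 did with the block (adjusted p = 0.0334) and both did with array weights. These genes were chosen after their values were seen, apart from Socs2 and Socs3. Members of further lists passed singly. The glutathione transferase Gstm6 fell (-2.77, adjusted p = 0.00844), as did Nlrc5, a regulator of antigen presentation genes (-1.49, adjusted p = 0.0232), and Mndal among genes of NZO loci (-3.01, adjusted p = 0.0370, and -2.63 with 0.0685 from its second probe set), where Mogat1 rose. The clock-linked gene Noct rose (1.53, adjusted p = 0.0406), as did the interferon-induced Gbp7 (1.76, adjusted p = 0.0274, and 1.01 with 0.162 from its second probe set), while Xaf1 of the same list fell by its brighter probe set only. Egr1 was the 1 immediate early gene past the test, and Cyp2c37 the 1 pericentral gene. Adjusted over the list alone, the higher and lower counts were 0 and 3 for glutathione, 0 and 1 for antigen presentation, 2 and 1 for NZO locus, 1 and 0 for circadian, 1 and 4 for interferon, 0 and 1 for immediate early and 0 and 3 for pericentral genes.

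None of the remaining 20 lists passed as a whole over 6 arrays, but several did under an alternative. Camera adjusted p was 0.0570 for interferon response (mean -0.32), 0.0653 for pericentral (-0.56), 0.0856 for neutrophil (0.11), 0.118 for immediate early (-0.40), and 0.130 for adipocyte (0.16), lipid-associated macrophage (0.11), insulin signalling (-0.36) and circadian (0.04) genes. It was 0.171 for bile duct (0.12), 0.189 for NZO locus (0.01), 0.210 for T and NK cell (0.09), 0.216 for erythroid (0.12), 0.323 for glycolysis (-0.23), 0.332 for B cell (0.00), 0.385 for exocrine pancreas (0.03), 0.396 for cholesterol synthesis (-0.24), 0.618 for periportal (-0.09), 0.658 for antigen presentation (-0.04), 0.755 for glutathione (-0.23) and 0.924 for amino acid and urea (-0.06) genes. The mean was below 0 and camera's direction upward for the periportal, antigen presentation and amino acid lists, and the glutathione list had a median of 0.08. Without BKS replicate 1 the neutrophil (adjusted p = 0.00678) and lipid-associated macrophage (0.0130) lists passed, without BKS replicate 2 the interferon (0.0188), pericentral (0.0427) and circadian (0.0471) lists, and without BKS replicate 3 the immediate early list (0.0309). Without NZO replicate 1 the periportal (adjusted p = 0.0180) and amino acid (0.000954) lists passed, without NZO replicate 2 the interferon (0.00607), pericentral (0.0128), immediate early (0.0447), insulin (0.0397), T and NK cell (0.0415) and cholesterol (0.0234) lists, and without NZO replicate 3 the pericentral list (0.0177). Among the 2 against 2 arrays the neutrophil (0.0174), lipid-associated macrophage (0.0116), erythroid (0.0194), periportal (0.0330) and amino acid (0.0128) lists passed. The amino acid list passed with repeated quantile normalization (adjusted p = 0.0111) and cyclic loess (0.000933), the circadian list with both (0.0429 and 0.0438) and with the mean of probe sets (0.0212), and the periportal list with cyclic loess (0.0236). The neutrophil list passed with array weights (0.0227), the lipid-associated macrophage list with array weights (0.0360) and the dim filter (0.0468), and the immediate early list with the mean of probe sets (0.0126) and the intensity trend (0.0437).

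The arrays titled number 1 stood apart from the other 4. RNA degradation on those arrays is argued against, since their beta-actin 3' minus 5' differences lay inside or below the range of the others (lowest of the number 1 arrays minus highest of the others, -1.04). The spiked-in controls, whose lowest value on the other arrays lay 0.879 above the highest on the number 1 arrays, are what first set these arrays apart, so they are no test of a batch as the cause. A further set of spiked-in controls, of poly-A RNA, averaged 5.93 and 5.92 on the number 1 arrays and 6.94 to 7.84 on the other 4. Neither set holds liver RNA, so for the controls these values argue against a difference between the animals alone. The labels name no batch. Whether the liver genes differed on these arrays through processing or between the animals cannot be told apart.

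The 3 mitochondrial lists were lower while the lists of PPAR alpha targets, lipid droplets and peroxisomal fatty acid oxidation were higher. Bright genes as a whole were lower in NZO, with a median log2 fold change of -0.33 at 11 to 13 on the log2 scale, -0.05 among the 2 against 2 arrays. All 3 mitochondrial lists lay within the central 95% of 10000 random lists matched on mean expression, so an intensity trend between the arrays may account for part or all of their shift, though complex I, at -0.42, passed with repeated quantile normalization (-0.14, adjusted p = 0.0359) but not with cyclic loess (-0.09, adjusted p = 0.192). The 3 higher lists lay at the 99.99th percentile or above, but so did lists that did not pass, mitochondrial fatty acid oxidation (99.99) and fatty acid synthesis (100), so this place does not mark them out. For these 3, random lists matched on mean expression averaged -0.19, -0.165 and -0.191, so the trend lowered genes of their brightness. This argues against the trend as the source of their higher means. The 3 kept their calls after repeated quantile normalization and after cyclic loess, which even out such trends. Under loess their means were 1.34, 0.51 and 0.51, against 1.14, 0.34 and 0.28. Removing a trend that lowers these lists would raise them anyway, so the kept calls are no test of it. A strain effect stays a hypothesis, since beta-actin truncation and strain cannot be separated here and 0 lists passed with an estimated correlation.

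Endothelial markers were higher and hepatocyte markers lower. A lower share of hepatocytes in the NZO samples would raise the other cell types alike. Among markers with a mean of at least 6, 16 endothelial ones exceeded 20 stellate ones by 0.448 (permutation p = 0.00482 over genes, which are not independent replicates, and 0.00964 adjusted over 4 comparisons), but by 0.285 among the 2 against 2 arrays (permutation p = 0.138). They exceeded 15 Kupffer markers by 0.200 (permutation p = 0.201, and 0.012 with permutation p = 0.952 in 2 against 2) and 5 bile duct markers by 0.296 (permutation p = 0.228, and 0.584 with permutation p = 0.0348 in 2 against 2). They exceeded hepatocyte markers by 0.843 (permutation p = 1e-05, the smallest possible), but this restates the list shifts that prompted it and adds no support. The whole hepatocyte list is also brighter (mean 12.3 against 6.74), and bright genes as a whole were lower in NZO. A change in composition and a change in the endothelial cells cannot be told apart, because the contrasts differ between cell types and between the array sets.

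Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many as 135 genes, the real one, and the highest other gave 0, but 10 splits cannot give a share under 0.05. Among genes called lower with a second probe set of mean at least 6, that probe set was also lower in 19 of 21 (90.5%, exact 95% binomial interval 69.6 to 98.8, against 57.1% of all such genes), and among genes called higher it was also higher in 8 of 8 (100%, interval 63.1 to 100), so strain variants under the probes stay open. Genes past the test formed 2 neighbouring pairs (shuffled mean 0.923, 95th percentile 3). With the block 99 neighbouring pairs formed, above the 95th percentile of 95 in shuffles matched on expression, consistent with shared strain haplotypes or local regulation. Of the 14 lists past the threshold, 9 lay outside the central 95% of matched random lists. Inside it lay the 3 mitochondrial lists, integrated stress (percentile 3.42) and skeletal muscle (percentile 96.42).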
